A study of Mus musculus with 2 samples.

How the data were processed

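RNA-seq was done on optic nerve of mice at postnatal day 12. The labels give 1 library of Hdac3 f/+; Olig1-cre animals, the control group, and 1 library of Hdac3 f/f; Olig1-cre animals, the Hdac3 cKO group, on a mixed strain background. Olig1-cre is a recombinase driven from the Olig1 gene, and f marks an Hdac3 allele that it can delete, so the control group carries 1 such allele. The number of animals per library is not given in the sources used here. Each library held RNA of both sexes, as described below, so it does not come from 1 animal alone. Per the labels' protocols, nerves were frozen on dry ice, total RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit.

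The authors deposited FPKM per gene (fragments scaled by transcript length and by a total of fragments) for each library, with the lower and upper bound of an interval and a status for every value, per the file headers. The submitters' processing notes name CASAVA, TopHat and Cufflinks and the mm9 genome build. The versions of these tools, the annotation, the read length, the total or normalisation mode behind the FPKM and the numbers of reads are not given in the sources used here. Counts and sequencing depth per library are therefore unknown, and the columns for transcript length and coverage are empty. The status column reads OK, LOWDATA (too few fragments to estimate) or HIDATA (too many fragments at a locus, which Cufflinks then skips). LOWDATA marks 356 values in each library, and HIDATA marks 0 values in the control-labelled library and 1 in the cKO-labelled library.

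Both tables hold 24460 entries, matched by symbol, transcription start site group and locus. They cover 23950 symbols, of which 268 have several entries. Such a symbol was represented by the entry with the highest summed FPKM. A gene was tested when its status was OK in both libraries and its FPKM was at least 1 in at least 1 library, which left 14154 genes. The difference was log2 of cKO FPKM plus a pseudocount of 1 over control FPKM plus the same pseudocount, on the deposited FPKM with no further scaling. A gene was counted lower or higher when this difference was at least 2-fold and the deposited intervals of the libraries did not overlap. With 1 library per group there is no replicate check, so no p-value was computed, and every count and difference describes these libraries, not the genotypes. The deposited intervals do not hold the variation between animals. They do not fully cover the estimation error within a library either, since many exclude their own FPKM (15.9% of genes with FPKM of at least 1 in the control-labelled library, 32.9% in the cKO-labelled library).

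A total of 30 gene lists with 416 distinct genes was fixed before the data were examined, together with the thresholds, the naming rule and most of the other settings tried. The lists came from general knowledge of the cell types and pathways. The main lists were myelin proteins, myelin lipid enzymes, oligodendrocyte transcription factors, oligodendrocyte precursor markers, newly formed oligodendrocyte markers, astrocyte markers and astrocyte fate regulators. The secondary lists covered cholesterol synthesis, reactive astrocyte genes, targets of STAT3, Notch, BMP and Wnt signalling, HDAC3 complex and acetyltransferases, and markers of microglia, endothelium, mural cells, meningeal fibroblasts, Schwann cells, neurons, photoreceptors, pigment cells and lens, skeletal muscle and red blood cells. Further secondary lists covered cell cycle genes, p53 targets, the interferon response, the unfolded protein and integrated stress response, immediate early genes and housekeeping genes. Across lists, 6 genes belong to several lists, and 1 list gene (Hbb-b2) has no entry.

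For each list with at least 3 tested members, the median log2 difference was placed among the medians of 10000 random lists of the same size. These were drawn from the tested genes and matched on mean log2 expression in 20 bins with seed 1. A list was said to stand apart when its percentile was below 2.5 or above 97.5. The random lists do not carry the co-expression of real lists, so the percentile is a description and not a probability.

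The text names Hdac3 and the 12 genes with the largest log2 difference in each direction among counted genes with FPKM of at least 5 in at least 1 library. Symbols with the name patterns of predicted genes, of small RNAs (such as Mir and Snor) and of families whose copies share reads (such as Rpl, Rps and Hist) were left out of that ranking. The name patterns do not catch every such gene, and DQ267102 and Pisd-ps1 passed them. For each list it draws on at most 4 members, the 2 with the highest mean FPKM and the 2 with the largest absolute difference. Genes named outside this rule are identified as such, except Gfap, Gpr37, Hmgcs1, Tcf7l2, Hba-a2 and Ptgds, which were also named after their values were seen, and some genes that it selects are not reported here.

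The alternatives planned before the data were examined were pseudocounts of 0.1 and 5, and scaling to the same sum, to the same upper quartile or to a median difference of 0. They also included summed entries per symbol, no minimum FPKM, a minimum of 5 in 1 library or of 1 in both, any status, thresholds of 1.5-fold and 3-fold, and intervals not required to separate. For lists, the random lists were also matched on the control library or not matched, and the mean replaced the median. The use of the interval midpoint in place of FPKM and the restriction to protein-coding symbols were chosen after seeing the data. For the latter, a gene annotation of another mouse assembly (GRCm38) was used for the class of each symbol only, and 99.7% of the 14154 tested symbols had a match.

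The procedure was tested on simulated data made from the control values for 18467 genes. It recovered 50 of 50 genes lowered 4-fold and 50 of 50 raised 4-fold, called 0 of 50 genes changed by 1.5-fold in each direction, and called 0 of 13314 unchanged genes. Of 200 random null lists, 5 fell outside the central 95% of random medians, and a list of 15 raised genes was found. The simulated library differed by counting error only, without variation between animals or dissections, and each value lay inside its interval. A change of 1.5-fold lies short of the 2-fold threshold by definition. The test therefore checks the calculation and gives no rate of false calls between the deposited libraries. The software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.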

Results

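Gene expression was measured by RNA-seq in whole optic nerve of mice at postnatal day 12, with 1 control library (Hdac3 f/+; Olig1-cre) and 1 Hdac3 cKO library (Hdac3 f/f; Olig1-cre). The study asks how HDAC3, a histone deacetylase, acts on the choice between the oligodendrocyte and astrocyte lineages. The deposited FPKM summed to 441867 in the control-labelled library and 557861 in the cKO-labelled library. FPKM was at least 1 for 13521 genes in the control-labelled library and 13839 genes in the cKO-labelled library. Read depth is unknown. The half-width of the deposited interval was taken as a percent of its midpoint, over 8770 genes with FPKM of at least 5 in both. Its median was 7.53% in the control-labelled library and 4.23% in the cKO-labelled library. No group has a replicate, so differences are given without a replicate check.

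Hdac3 itself (chromosome 18, 38096625 to 38114642, mm9) was at 36.4 FPKM in the control-labelled library, with a deposited interval of 31.4 to 35.6. It was at 38.0 FPKM in the cKO-labelled library, with an interval of 33.4 to 36.0. Both values lie above their own intervals. The log2 difference was 0.06. The interval bounds give -0.09 to 0.19, a range that rests on intervals that exclude both values. The sign of the Hdac3 log2 difference depends on the scaling, and it was -0.01 after scaling to the same upper quartile, -0.06 after centring on the median and -0.26 after scaling to the same sum. In none of these was Hdac3 at least 2-fold lower in the library labelled cKO at the level of the whole gene. The values do not show which exons the reads came from, so they leave the genotype labels unchecked, and every direction below refers to the library labelled cKO against the library labelled control.

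Of 14154 genes tested, 638 (4.51%) were at least 2-fold lower in the cKO-labelled library with separate intervals, and 669 (4.73%) were higher. Another 65 genes were lower and 141 higher by the same size with overlapping intervals. The median log2 difference of all tested genes was 0.12, and this shift depends on the scaling. It was 0.05 after scaling to the same upper quartile and -0.16 after scaling to the same sum. Of the genes counted, 51.2% were higher on the deposited scale (638 lower, 669 higher), 43.3% after scaling to the same upper quartile (696 lower, 531 higher), 36.6% after centring on the median (761 lower, 439 higher), and 18.3% after scaling to the same sum (960 lower, 215 higher). Symbols of small RNAs made up 11.4% of the FPKM summed over 1 entry per symbol in the control-labelled library and 25.3% in the cKO-labelled library, which weighs on the scaling to the same sum. The percentiles of gene lists below compare a list with other genes of the same libraries, so a common shift enters both sides.

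The genes with the largest difference among those lower in the cKO-labelled library were mostly genes of myelin and oligodendrocytes. Mbp (chromosome 18, 82644515 to 82755029) was at 15976 FPKM in the control-labelled library and 2013 in the cKO-labelled library, a log2 difference of -2.99. Omg went from 37.9 FPKM in control to 3.94 in cKO (log2 -2.98), Ermn from 48.5 to 5.55 (log2 -2.92) and Tspan2 from 354 to 46.7 (log2 -2.89). Ugt8a was at 303 and 41.0 FPKM (log2 -2.86), Fa2h at 132 and 17.8 (log2 -2.82), and Bcas1 at 410 and 58.9 (log2 -2.78). Map6d1 was at 57.5 and 7.71 FPKM (log2 -2.75) and Tmem88b at 94.3 and 13.5 (log2 -2.72). Also among them were Tnni1, a troponin of slow muscle, at 25.5 and 2.67 FPKM (log2 -2.85), and Cga, a pituitary hormone subunit, at 6.54 and 0.0235 FPKM (log2 -2.88).

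Among genes higher in the cKO-labelled library, Gdf10 (chromosome 14, 34736773 to 34748468) was at 31.0 FPKM in the control-labelled library and 189 in the cKO-labelled library, a log2 difference of 2.57. Itih3 (chromosome 14, 31721760 to 31736773) was at 7.90 and 46.4 FPKM (log2 2.41), Gli1 at 1.11 and 9.99 (log2 2.38), and C3 at 6.57 and 37.2 (log2 2.34). Ifi27l2a was at 12.7 and 57.2 FPKM (log2 2.09), Fam107a at 61.2 and 257 (log2 2.05), and Prokr2 at 1.35 and 7.95 (log2 1.93). Orm2 was at 0.604 and 7.76 FPKM (log2 2.45) and Cox8b at 1.59 and 10.4 (log2 2.14), and the cKO values of both lie above their own intervals (5.23 to 6.65 and 3.97 to 5.96). The cKO values of Gdf10 (interval 172 to 177), Itih3 (42.3 to 44.5), C3 (35.3 to 36.9) and Fam107a (238 to 243) also lie above theirs. So do the control values of Gdf10 and Fam107a. Snhg9 was at 8.87 and 53.2 FPKM (log2 2.46), both above the upper bounds of their intervals, 3.17 and 8.25. Pisd-ps1, a pseudogene that shares reads with its parent gene, was at 0.0972 and 6.58 FPKM and is uncertain. DQ267102 was listed at 0 in the control-labelled library and at 113 FPKM in the cKO-labelled library, where its interval was 0.161 to 1.93, so its level is uncertain too.

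**Figure D1:**
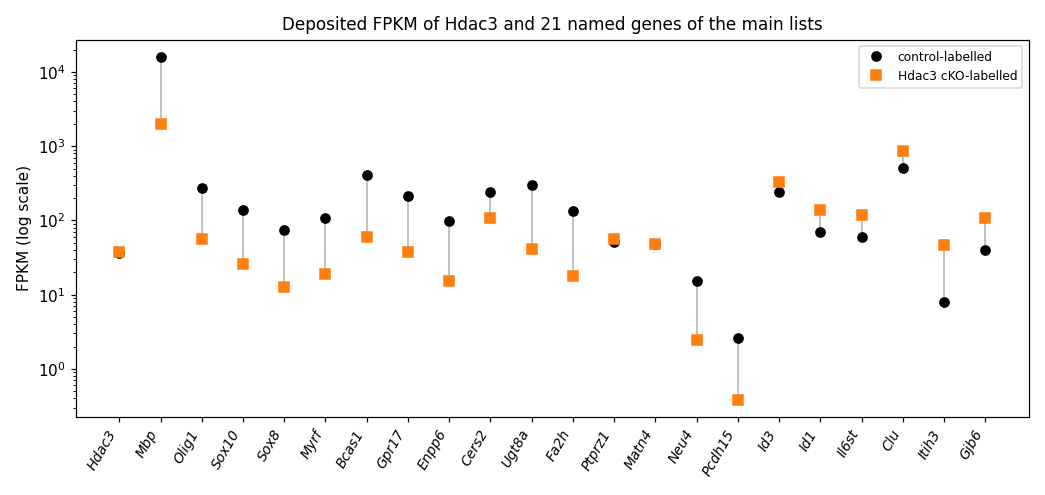
FPKM (log scale) of Hdac3 and 21 named members of the main gene lists, with 1 point for the control-labelled library (circles) and 1 for the cKO-labelled library (squares). Hdac3 was at 36.4 and 38.0 FPKM, Mbp was at 15976 and 2013 FPKM, and Gjb6 was at 40.4 and 107 FPKM.

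All 18 myelin protein genes were lower in the cKO-labelled library by the size and interval rule. Their median log2 difference was -2.59, with a middle 50% of -2.70 to -2.20, below all 10000 random lists of matched expression. The smallest difference in this list was -1.24 for Gpr37. Of 10 myelin lipid enzymes, 6 were lower and 0 higher, with a median of -1.32 at percentile 0.01. Cers2, the most abundant of them with Ugt8a, was at 238 FPKM in control and 109 in cKO (log2 -1.13). Of 21 measured genes of cholesterol synthesis and uptake, 16 were lower and 0 higher, and their median of -1.35 lay below all random lists. Mvd was at 58.0 FPKM in control and 13.8 in cKO, and Fdps at 224 and 58.2 (log2 -1.92). Hmgcs1 was listed at 0 in both libraries and was not tested.

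Transcription factors of the oligodendrocyte lineage were lower in the cKO-labelled library for 9 of 10 genes, with a median log2 difference of -2.32, below all random lists. Sox8 was at 73.7 FPKM in control and 12.8 in cKO (log2 -2.43), Myrf at 106 and 19.1 (log2 -2.42), Sox10 at 140 and 25.6 (log2 -2.40) and Olig1 at 273 and 56.4 (log2 -2.26). Olig2, named here after its values were seen, was at 92.2 and 17.8 FPKM (log2 -2.31). The exception was Tcf7l2, at 14.8 and 8.11 FPKM (log2 -0.79), which was lower by the rule after scaling to the same sum. Of 11 markers of newly formed oligodendrocytes, 8 were lower and 0 higher, with a median of -1.75, below all random lists. Enpp6 was at 98.8 FPKM in control and 15.3 in cKO (log2 -2.62), and Gpr17 at 215 and 37.2 (log2 -2.50).

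Markers of oligodendrocyte precursors were lower for 5 of 15 genes and higher for 0. Their median log2 difference of -0.79 lay below all random lists, and the members spread from -2.22 to 0.32. Neu4 was at 15.2 FPKM in control and 2.47 in cKO (log2 -2.22). Pcdh15 was at 2.62 and 0.385 FPKM (log2 -1.39, and -0.50 with a pseudocount of 5). Matn4, at 48.9 and 48.8 FPKM, and Ptprz1, at 51.8 and 56.4, did not meet the rule. Pdgfra and Cspg4, named here after their values were seen, did not meet it either. Pdgfra was at 35.4 FPKM in control and 38.8 in cKO (log2 0.13), and Cspg4 was at 9.93 and 6.93 (log2 -0.46). Values from whole nerve do not separate precursors from other cells that may express a marker. Members near 0 therefore do not show that precursors were spared.

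Astrocyte markers gave differences of the opposite sign. Of 27 measured, 6 were higher in the cKO-labelled library and 0 lower, and 25 of the 27 differences were above 0. The median log2 difference was 0.74, with a middle 50% of 0.55 to 0.90, above all random lists. It was 0.40 after scaling to the same sum, where 2 markers were higher and 1 lower. Beside Itih3, Gjb6 was at 40.4 FPKM in control and 107 in cKO (log2 1.39). Clu was at 502 and 868 FPKM (log2 0.79) and did not meet the rule. The differences below 0 were those of Fabp7, at 220 and 122 FPKM (log2 -0.85), and Aqp4, at 181 and 153 (log2 -0.24), both named after their values were seen. Gfap was at 3997 FPKM in the control-labelled library. In the cKO-labelled library it carried the HIDATA status and was listed at 0, so no difference can be given for it.

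Of 13 transcription factors and receptors that promote astrocyte formation, 0 met the rule in either direction. Their median log2 difference was 0.45 at percentile 97.6, with 12 of 13 differences above 0, while their mean of 0.43 lay at percentile 93.3. Id1 was at 69.0 FPKM in control and 136 in cKO (log2 0.97), Il6st at 60.6 and 119 (log2 0.96) and Id3 at 239 and 326 (log2 0.45). Nfia (13.3 and 19.5 FPKM, log2 0.52) and Stat3 (46.6 and 51.4 FPKM, log2 0.14) were named after their values were seen. Of 26 genes of reactive astrocytes, 10 were higher and 0 lower, with a median of 0.83, above all random lists. After scaling to the same sum, 2 were higher, with a median of 0.51. Serping1 was at 143 FPKM in control and 403 in cKO (log2 1.49), Serpina3n at 223 and 421 (log2 0.91), and Vim at 1762 and 2250 (log2 0.35). Of 10 STAT3 targets, 3 were higher, with a median of 0.73 at percentile 99.9, while their mean of 0.67 lay at percentile 93.3, and after scaling to the same sum 1 was higher. Cebpb was at 3.53 and 14.3 FPKM (log2 1.75), Cebpd at 4.79 and 12.0 (log2 1.17), and Hif1a at 21.0 and 18.5 (log2 -0.17).

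Targets of other pathways did not stand apart in the main setting. The median log2 difference was -0.03 for 7 Notch targets (percentile 20.3), 0.49 for 9 BMP targets (percentile 95.7) and 0.48 for 9 Wnt targets (percentile 96.9). With a pseudocount of 0.1 the BMP list (percentile 97.7) and the Wnt list (percentile 99.1) stood apart. Of 15 other settings, the BMP list did not stand apart in 12 and the Wnt list in 11. Smad7 was lower, at 12.5 FPKM in control and 4.68 in cKO (log2 -1.25), while Id4 was at 140 and 240 (log2 0.77). Notum was higher, at 2.06 and 7.90 FPKM (log2 1.54). Of 12 genes for class I histone deacetylases, corepressor subunits and acetyltransferases, 0 met the rule, and their median was -0.00 at percentile 25.4. Hdac1 was at 47.5 FPKM in control and 50.7 in cKO (log2 0.09), Hdac2 at 36.1 and 28.3 (log2 -0.34), and Hdac8 at 7.10 and 12.6 (log2 0.75). The gene for the acetyltransferase p300, Ep300, named here for the study's question, was at 8.92 and 9.48 FPKM (log2 0.08).

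**Figure D2:**
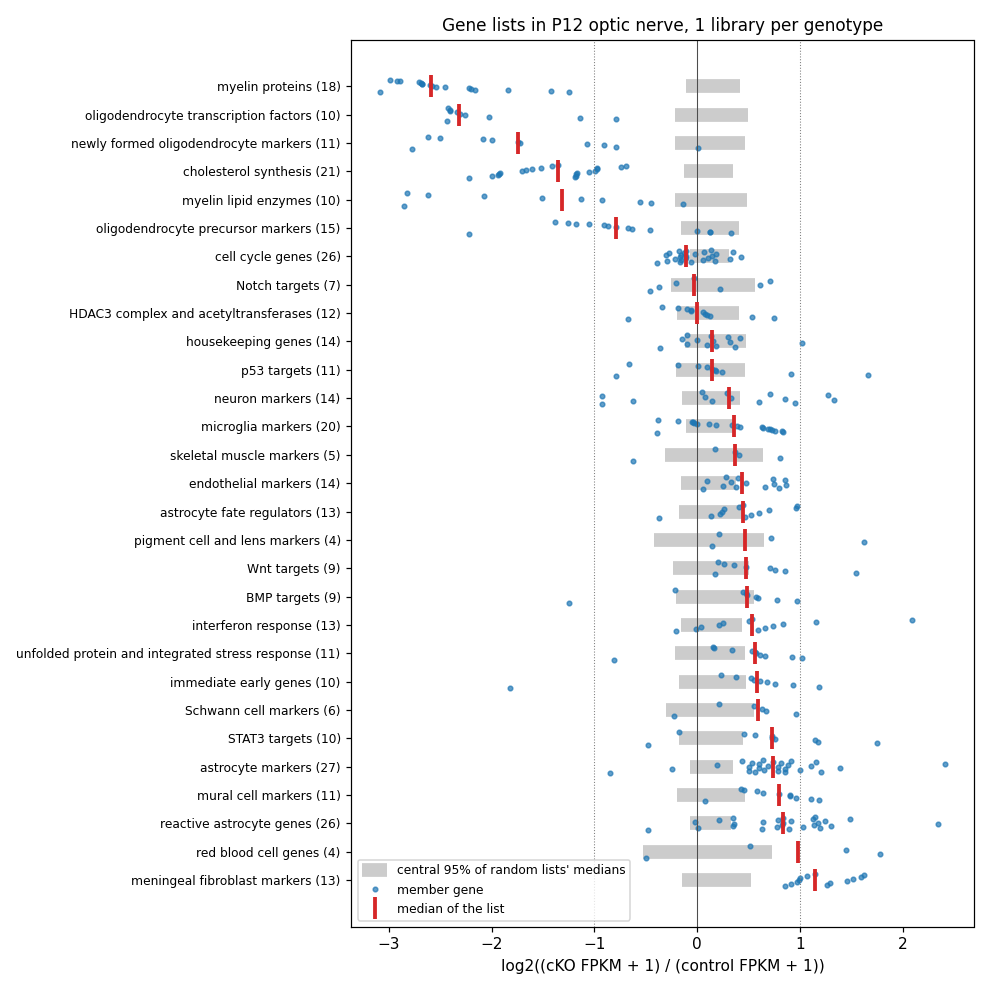
Log2 difference, cKO-labelled over control-labelled library, of the measured members (points) of 29 gene lists, with the list median (red bar) and the central 95% of medians of 10000 random matched lists (grey). The medians run from -2.59 for myelin proteins to 1.15 for meningeal fibroblast markers.

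For markers of other cell types of the nerve, list medians were above 0. Of 13 meningeal fibroblast markers, 9 were higher, with a median log2 difference of 1.15 and a middle 50% of 0.99 to 1.46, above all random lists. After scaling to the same sum, 4 were higher, with a median of 0.82. Dcn was at 138 FPKM in control and 429 in cKO (log2 1.63), Lum at 30.5 and 94.1 (log2 1.59), Igf2 at 679 and 1665 (log2 1.29), and Col1a2 at 335 and 704 (log2 1.07). Of 11 mural cell markers, 2 were higher (0 after scaling to the same sum), with a median of 0.80 at percentile 99.9, and Vtn was at 160 and 312 FPKM (log2 0.96). For 14 endothelial markers the median was 0.44 at percentile 99.0, for 20 microglia markers 0.36 at percentile 97.6, and for 6 Schwann cell markers 0.59 at percentile 98.3, with 0 members of these lists past the rule. The endothelial list did not stand apart by its mean (percentile 91.6). The microglia list, with 7 of 20 differences below 0, and the Schwann cell list each stood apart in only 10 of 15 other settings. C1qb was at 69.8 FPKM in control and 125 in cKO (log2 0.83), and Cldn5 at 64.1 and 68.5 (log2 0.09). Of the 4 measured genes of red blood cells, 2 were higher, with a median of 0.98 at percentile 99.6 (0.51 at percentile 97.1 with no minimum FPKM). Hba-a1 was at 40.9 and 143 FPKM (log2 1.78), although its near-identical copy Hba-a2 shares reads with it.

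Lists of neurons and neighbouring tissues did not stand apart in the main setting. The median log2 difference of 14 neuron markers was 0.31 (percentile 90.1), and 0.65 (percentile 99.8) with a minimum FPKM of 5. Nefh was at 4.88 FPKM in control and 13.8 in cKO (log2 1.33), Nefl at 11.6 and 29.5 (log2 1.28), and Gap43 at 49.9 and 25.8 (log2 -0.92). The median was 0.47 for 4 pigment cell and lens markers (percentile 88.9) and 0.37 for 5 skeletal muscle markers (percentile 85.7). With no minimum FPKM the pigment cell and lens list stood apart (0.13 at percentile 98.0). Only 1 of 15 photoreceptor markers, Rom1, reached the minimum FPKM, at 4.55 in control and 9.34 in cKO.

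Of 26 cell cycle genes, 0 met the rule, and their median log2 difference of -0.11 lay at percentile 0.97, while their mean of -0.03 lay at percentile 11.4. Mki67 was at 8.996 FPKM in control and 6.63 in cKO (log2 -0.39). The median was 0.54 for 13 interferon response genes (percentile 99.4), 0.56 for 11 genes of the unfolded protein and integrated stress response (percentile 99.1) and 0.58 for 10 immediate early genes (percentile 99.2). By their means these lists did not stand apart (percentiles 94.7, 93.6 and 83.3). Members past the rule were Ifi27l2a and Isg15 (log2 1.16), Atf5 (log2 1.01), and Btg2 (log2 1.19), which were higher, and Arc, which was lower at 7.56 FPKM in control and 1.42 in cKO (log2 -1.82). The median was 0.15 for 11 p53 targets (percentile 59.8), of which Cdkn1a was higher, at 9.94 and 33.6 FPKM (log2 1.66). For 14 housekeeping genes the median was 0.14 (percentile 43.1). B2m was higher, at 126 FPKM in control and 257 in cKO (log2 1.02), and Actb was at 880 and 823 (log2 -0.10). The sign of the medians of the Notch, HDAC3 complex, p53, housekeeping and skeletal muscle lists changed with the scaling or another setting.

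Of the 29 lists with a percentile, 7 stood apart on the lower side and 13 on the higher side, and 9 did not stand apart. On the higher side, only the astrocyte marker, reactive astrocyte, mural cell and meningeal fibroblast lists also stood apart in each of 15 other settings. On the lower side, all but the cell cycle list did. Of 60 named genes that met the rule, 17 fell short of it under at least 1 other pseudocount or scaling. Among these were Acta2, Anpep, Arc, Atf5, B2m, Btg2, Cebpd, Col1a2, Crygs, Igf2, Isg15, Nefh, Nefl, Notum, Pcdh15 and Smad7.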

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

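The tests of the Gfap value were chosen only after the result was seen. The Gfap value was singled out because the control-labelled library holds a strong signal, 3997 FPKM, for a gene that the comparison had to leave out. The values outside their own intervals were singled out because the interval columns carry information that the FPKM column alone does not show.

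Gfap was at 3997 FPKM in the control-labelled library and was listed at 0 in the cKO-labelled library. The number of Gfap entries with the HIDATA status in the cKO-labelled library was 1, and no other gene had it, which argues against a loss of Gfap transcripts, since that status is given for too many fragments. The deposited intervals imply that the cKO-labelled library is 2.93 times as deep as the control-labelled library (middle 50% of 2.60 to 3.29 over 8770 genes), if their widths reflect counting error. At an unchanged level the Gfap locus would then hold 0.949 times the fragments of the fullest locus that passed, Ptgds. A skipped locus is a likely source of the 0. This rests on the HIDATA status, since the ratio alone would not put Gfap past Ptgds. By the median depth, a locus fuller than any that passed would put Gfap at 1.05 times its control level or more. A depth nearer the upper end of the middle 50%, 3.29, would lower that value, so 1.05 is not a firm lower bound. It also rests on the interval widths alone. Whether Gfap differed between the libraries or with the genotype therefore stays open.

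In the cKO-labelled library, 4551 of 13839 genes with FPKM of at least 1 (32.9%) had an FPKM outside its own deposited interval. In the control-labelled library this held for 2149 of 13521 genes (15.9%). Replacing FPKM by the midpoint of its interval gave 636 genes lower and 596 higher, against 638 and 669 with FPKM.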

How the results depend on the processing

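The settings with interval midpoints and with protein-coding symbols only were chosen after the results were seen. In each setting run, the medians of the myelin, myelin lipid, oligodendrocyte transcription factor, newly formed oligodendrocyte, precursor and astrocyte lists kept their direction and side of the threshold. The ranges were -2.92 to -2.42 for myelin proteins, -1.07 to -0.52 for precursors and 0.40 to 0.74 for astrocyte markers. The astrocyte fate regulators no longer stood apart with a pseudocount of 0.1 (median 0.49), after scaling to the same upper quartile (0.37) or by their mean (0.43). The Hdac3 log2 difference was -0.26 after scaling to the same sum. Genes higher numbered 1156 with a pseudocount of 0.1, 282 with 5, 215 with the same sum, 439 when centred, 2262 at 1.5-fold and 91 at 3-fold. Genes lower numbered 339 with a pseudocount of 5, 960 with the same sum, 1253 at 1.5-fold and 247 at 3-fold. Astrocyte markers higher numbered 2 with the same sum, 19 at 1.5-fold and 1 at 3-fold, and 1 was lower with the same sum and at 1.5-fold. At 1.5-fold, 4 fate regulators were higher. Precursor markers lower numbered 2 with a pseudocount of 5, 8 with the same sum, 3 with a minimum FPKM of 5 in 1 library, 3 with 1 in both, 10 at 1.5-fold and 1 at 3-fold. The fold thresholds and minimum FPKM act through their own definition, and for the other settings the cause was not tested. Of the secondary list medians, 299 values kept their side of the threshold, 10 moved past it (in the BMP, Wnt, neuron and pigment cell and lens lists) and 18 fell short of it. By their mean, the STAT3, Schwann cell, endothelial, microglia, interferon, stress response, immediate early and cell cycle lists no longer stood apart. Microglia and Schwann cell lists kept their call in 10 of 15 settings each. Of the values of named genes, 749 kept their side, 7 moved past it and 35 fell short. No value past its threshold changed sign, while values short of it, such as Hdac3, did. With 1 library per group, no replicate could be left out, and depth is unknown, so a floor for genes listed at 0 cannot be given.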

Other observations

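The tests of explanations for the marker lists and for Hdac3, and the scalings of Y-linked genes, Ptch1 and Hhip, were chosen only after the results were seen, while the list medians and the Hdac3 difference themselves were fixed beforehand.

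Y-linked genes and Xist were present in both libraries, so both hold RNA of both sexes. Ddx3y was at 7.72 FPKM in the control-labelled library and 4.59 in the cKO-labelled library, Eif2s3y at 17.1 and 8.66, and Xist at 21.9 and 23.7. The log2 differences of Ddx3y, Eif2s3y, Kdm5d and Uty were below 0 on the deposited scale (-0.64, -0.90, -0.51 and -0.31) and under each other scaling, and Eif2s3y was lower by the 2-fold rule after centring (-1.02) and scaling to the same sum (-1.20). The share of RNA from males in each library is not given in the sources used here. Like Cga, the pituitary hormone gene Tshb was lower, at 2.97 FPKM in control and 0.356 in cKO, while Prl was listed at 0 in both libraries and Gh at 0 in control and 0.0164 in cKO. Atp6v0c was at 66.8 and 219 FPKM and its pseudogene Atp6v0c-ps2 at 155 and 24.7, while their sum was 221 and 243, so their separate values are uncertain. These genes were named after their values were seen. Ptch1 and Hhip were chosen as further Hedgehog targets once Gli1 was seen to be higher, and before their own values were seen. Ptch1 was higher, at 8.70 FPKM in control and 18.5 in cKO (log2 1.01), but fell short of 2-fold after scaling to the same upper quartile (0.94), centring (0.89) or scaling to the same sum (0.70). Hhip was lower, at 6.57 and 1.69 FPKM (log2 -1.49), also under these scalings.

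The medians of the astrocyte, mural cell and meningeal fibroblast marker lists stood above those of their random lists in each setting run, and those of the microglia, endothelial and Schwann cell lists in some. A common scaling difference as the sole source is argued against by the astrocyte median, which lay 0.62 above the median of all tested genes on the log2 scale. This value draws on the same list result as the percentile above and adds no separate test. The astrocyte median of 0.74 lies above those of the microglia (0.36), endothelial (0.44) and Schwann cell (0.59) lists. It lies below that of the mural cell list (0.80). With medians spread this widely, this place does not decide whether a lower share of oligodendrocyte RNA accounts for the astrocyte markers. Higher values were not confined to astrocyte markers, since the mural cell median lay 0.33 above the central 95% of its random lists. That repeats the list result above, so it is no separate test of astrocyte RNA rising alone. For meningeal fibroblast markers, a lower oligodendrocyte share as the sole source is argued against by the microglia and endothelial markers. The lower quartile of the fibroblast differences (0.99) lay 0.24 above the higher upper quartile of those lists. The mural cell list, left out of that comparison, had an upper quartile of 0.93, so against it the gap is small. More sheath tissue in the dissection, a higher level in fibroblasts and an added rise in astrocytes stay open, as does the genotype, and they stay open too for the reactive astrocyte genes, whose median of 0.83 lies between those of the mural cell and fibroblast (1.15) lists.

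Hdac3 was not at least 2-fold lower in the cKO-labelled library, and the Hdac3 log2 difference was 0.0612 on the deposited scale and -0.26 after scaling to the same sum. Transcripts from cells without cre, or from exons outside the deleted segment, could account for this, and the values per gene cannot decide it. The control group also carries 1 deletable allele. By design its Hdac3 is reduced in recombined cells too, which leaves a smaller difference to detect. Exchanged labels cannot be told apart from the stated ones by Hdac3 either, since its difference relative to the median of all genes was -0.0587. Values per exon, or from sorted cells of the oligodendrocyte lineage, would test both.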
